A study of Homo sapiens with 12 samples.

How the data were processed

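The analysis used 12 Affymetrix arrays of ML-2 cells, a human acute myeloid leukaemia line. Per the labels, cells received 2 µM SGI-110 or solvent for 24 h and then 5 µM ASTX660 or solvent for 9 h, giving 4 groups of 3 arrays. The SGI-110 single treatment is given as 33 h. Per the series design, the 3 arrays of a group came from 3 independent experiments, and the titles carry the numbers 2, 9 and 13. Those numbers were read as experiment numbers, which the labels do not state, and they carry no order. Per the labels' protocols, cRNA was made from 100 ng of total RNA with a 3' IVT PLUS kit and labelled with biotin.

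The deposited values are log2 intensities from RMA, per the submitters' processing notes, which name the affy package without a version. They held 54675 probe sets for each of the 12 arrays, ranged from 2.078 to 14.38, and had array medians between 4.688 and 4.774. Whether all arrays were normalized in a single RMA run is not given in the sources used here. No further transformation was applied before the tests. All changes are differences of RMA log2 intensities, which compress large ratios at low intensity, so folds are array ratios and not molecule counts.

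Probe sets were linked to genes with the platform annotation. Of 54675 probe sets, 42898 were listed there, 11777 were not, and 1801 carried several symbols or gene identifiers and were set aside. Of the 41097 with 1 symbol, 41091 were used after control probe sets were removed, and 41043 matched the gene table. Each gene was read from the probe set with the highest mean over all 12 arrays, a choice blind to group. A gene was tested when that probe set exceeded the array median in at least 3 arrays, which kept 12689 of 19775 genes. Among the tested genes 8164 had more than 1 probe set. Genes of near-identical families, such as HLA-B and HLA-C, the metallothioneins, and NCF1 with its pseudogene copies, are named with the limit that their probes can read relatives.

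Tests used limma 3.58.1 in R 4.3.3 with 1 mean per group, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the 12689 genes within each comparison. A gene was called at an adjusted p under 0.05. The model had 8 residual degrees of freedom and the median prior degrees of freedom were 5.927. Comparisons were SGI-110 with solvent, ASTX660 with solvent, the combination with solvent, the combination with SGI-110, the combination with ASTX660, and the interaction, meaning the combination change minus the sum of the single-agent changes. With 3 arrays per group the precision is limited, and the median standard error was 0.085 log2 units, or 0.12 for the interaction.

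The groups, the comparisons, the filter, the threshold, 20 gene lists and the alternative settings were fixed before the data were examined. The lists covered p53 targets, extrinsic apoptosis and death receptors, intrinsic apoptosis and the BCL2 family, inhibitor of apoptosis proteins, NF-kB targets, interferon-stimulated genes, cancer-testis genes, antigen presentation, G1/S and replication, G2/M and mitosis, DNA methylation and decitabine metabolism, the integrated stress and unfolded protein responses, oxidative and heat stress, MYC targets and ribosome synthesis, myeloid maturation, granule genes, the HOXA and MEIS1 programme, and erythroid, lymphoid, and fibroblast or epithelial markers. They were written from general knowledge and are not a published collection. Lists were tested with camera at an assumed inter-gene correlation of 0.01, adjusted over the 20 lists, and retested with an estimated correlation and with fry. Members were also adjusted over each list alone. Another 5 lists were added after the data were seen and are described as such. They covered cholesterol synthesis and uptake, fatty acid synthesis, ligands of NK and T cells, lysosome and autophagy, and amino acid transport and serine synthesis. Some lists share members, so their calls are not separate findings. FAS and TNFRSF10B are in the p53 and extrinsic lists, BAX in the p53 and intrinsic lists, and CD86 in the myeloid and ligand lists. ASNS, PHGDH, PSAT1, SLC7A11 and SLC3A2 are in the stress response and amino acid lists.

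Named genes followed a rule. For each comparison these were the 10 highest and 10 lowest log2 changes among called genes whose arrays did not overlap between groups, up to 4 members of each list with the smallest adjusted p, and 22 apoptosis and methylation genes named whatever their values, of which 18 were tested. The text leaves some of these out for length, those last in each ranking first, and leaves out others whose call another probe set choice ended. Genes outside that rule are stated to have been chosen after values were seen.

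The experiment number was used as a block only as an alternative. Deviations from the group mean had to correlate above 0.1 between arrays of the same number, for every number. For numbers 2, 9 and 13 the correlations were 0.377, 0.367 and 0.572 for SGI-110 with solvent, 0.321, 0.471 and 0.55 for ASTX660 with solvent, 0.15, 0.159 and 0.541 for the combination with solvent, and 0.208, 0.484 and 0.544 for the combination with SGI-110. For the combination with solvent, numbers 2 and 9 did not correlate best with their own number. By the 0.1 rule the numbers were taken to pair the arrays in these 4 comparisons, a pairing read from the titles and the values and not stated in the labels. In planted tests on the same design with 200 of 12689 genes changed, limma recovered 42% of genes changed 1.25-fold and 98% of those changed 1.5-fold for SGI-110 against solvent, with 2.87% of calls false. For ASTX660 against solvent the values were 42%, 96% and 2.31%, for the combination against SGI-110 40%, 100% and 6.11%, and for the interaction 22%, 58% and 3.47%. The planted arrays had independent noise without experiment effects, and the fit had no block. The 200 genes changed 1.25-fold, 1.5-fold, 2-fold or 3-fold, 50 at each. Strong changes ease the adjusted threshold, so these shares do not carry over to comparisons without them, such as ASTX660 against solvent. Methylation, protein levels, cell death measurements and raw intensity images were not used here.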

Results

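ML-2 cells, a human acute myeloid leukaemia line, were profiled on 12 arrays after solvent, SGI-110, ASTX660 or the combination. SGI-110 is guadecitabine, a hypomethylating agent that releases decitabine, and was given at 2 µM, for 33 h alone or for 24 h before ASTX660 was added. ASTX660 antagonises inhibitor of apoptosis proteins and was given at 5 µM for 9 h. Whether SGI-110 stayed on during the 9 h with ASTX660 is not given in the sources used here. The combination against SGI-110 and the interaction may therefore hold a difference in SGI-110 exposure as well. Each group held 3 arrays from 3 independent experiments. Values were RMA log2 intensities, 12689 genes were tested with limma, and changes are given as log2 differences with folds.

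The arrays separated by SGI-110. The first principal component held 51.2% of the variance and parted arrays with SGI-110 from arrays without it. The second (13.9%) set the arrays numbered 13 apart, and the third (11.7%) set ASTX660 array 2 apart at a score of 16.95, against −9.277 to 4.108 for the others. Correlations within a group were 0.9948 to 0.998 and between groups 0.9872 to 0.9984.

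**Figure D1:**
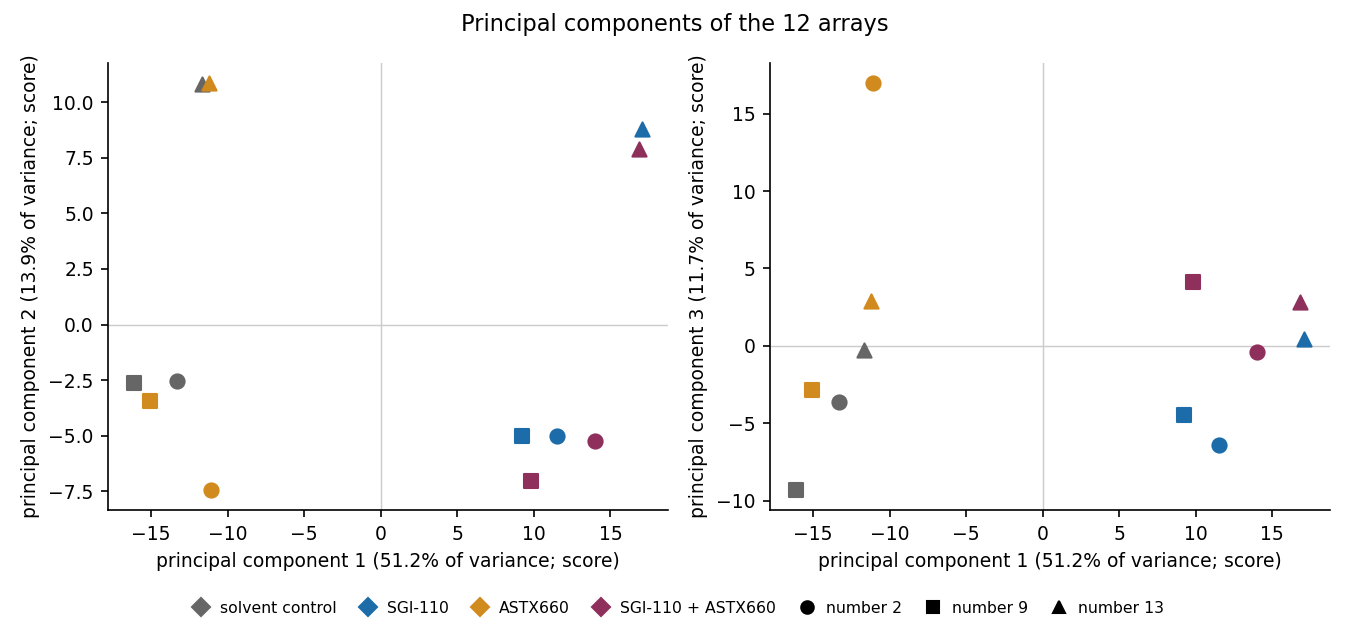
Scores of the 12 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in units of centred log2 intensity over 12689 genes, 1 point per array, coloured by treatment and shaped by experiment number. Component 1 (51.2%) parted SGI-110-treated arrays from the rest, and ASTX660 array 2 stood apart on component 3 (11.7%).

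SGI-110 alone raised the cell-cycle inhibitor CDKN1A and the p53 targets TP53I3, TP53INP1, PLK2 and SESN1. TKTL1, MAEL and HORMAD1, which are known as germline or cancer-testis genes, rose as well, and so did the detoxifying enzyme MGST1, the acute-phase gene HP and the chemokine CCL2. Fewer genes fell far, among them AFF3, a transcription elongation factor gene, NKD2, an inhibitor of WNT signalling, MANEAL, KATNAL2 and BCAT1, a branched-chain amino acid transaminase. Rises included TKTL1 (3.82 log2 units, 14.15-fold, limma adjusted p = 4.27e-07) and TP53I3 (3.82, 14.11-fold, adjusted p = 5.84e-08), followed by MGST1 (2.58, 5.996-fold), CDKN1A (2.33, SE 0.116, 5.029-fold, adjusted p = 4.96e-08), TP53INP1 (2.27), MAEL (2.19), HP (2.19), PLK2 (2.02), HORMAD1 (2.00) and CCL2 (1.94, adjusted p = 0.00594). Solvent means of TKTL1, MGST1 (4.35), TP53INP1 (4.66), MAEL (3.80) and HORMAD1 (3.56) lay below every array median (4.688 to 4.774), so their folds start near background and are not exact. Mean CDKN1A went from 8.131 (SD 0.211) to 10.46 (SD 0.176). AFF3 fell 2.829-fold (adjusted p = 0.000335), MANEAL by 1.29 (adjusted p = 1.2e-05), KATNAL2 by 1.27, NKD2 by 1.10 and BCAT1 by 0.79. limma called 1955 genes, 1206 higher and 749 lower (61.7% higher), and 100 of them changed at least 2-fold, 96 higher and 4 lower. The 3 SGI-110 arrays lay all above or all below the 3 solvent arrays in 1945 of these calls and in 36.2% of all genes, where chance gives 10%. The split of calls depended on scaling: 43.6% of 2297 calls were higher after median centring and 57.6% of 2158 after quantile normalization. Blocking on experiment number gave 3202 calls, and leaving out solvent array 9 or SGI-110 array 13 gave 1239 or 1289.

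Death receptor genes rose with SGI-110. FAS, TNFRSF10B, which encodes TRAIL receptor 2, and the ligand gene TNF rose, as did BAX, which permeabilises mitochondria, while XIAP and BIRC2, encoding proteins that ASTX660 binds, did not pass the test. Of 32 tested p53 targets 26 rose, 0 fell and 6 did not pass (28 and 0 adjusted over the list alone), with a median of 0.75. TP53I3, CDKN1A, TP53INP1 and SESN1 (1.57) led this list, which camera called higher (adjusted p = 1e-28) and which was the only list called with an estimated correlation (adjusted p = 0.0214). Of 20 extrinsic apoptosis genes 6 rose, 0 fell and 14 did not pass (8 and 0 over the list alone): FAS rose by 1.49 (SE 0.0972, 2.818-fold, limma adjusted p = 5.8e-07), TNFRSF10B by 0.95 (SE 0.0795, 1.927-fold, adjusted p = 7.75e-06) and TNF by 0.65 (1.572-fold, adjusted p = 0.000149). TNFRSF10A rose by 0.34 (adjusted p = 0.0141), a call lost without solvent array 9 (0.0685) or SGI-110 array 13 (0.0698), over a range of 0.00181 to 0.149 among alternatives. TNFSF10, encoding the ligand TRAIL, rose by 0.43 (adjusted p = 0.0332), a call lost without solvent array 2 (0.0694), solvent array 9 (0.122), solvent array 13 (0.0543), SGI-110 array 2 (0.111) or SGI-110 array 13 (0.102), range 0.00252 to 0.156. The probe sets of the TNFRSF10 genes can read relatives. The extrinsic list was higher by camera (median 0.17, adjusted p = 0.000323, and adjusted p = 0.199 with an estimated correlation). Of 18 intrinsic apoptosis genes 4 rose, 2 fell and 12 did not pass (5 and 2 over the list alone), with camera adjusted p = 0.116 and a median of 0.09, though fry (0.0152) and a test without the brightness filter (0.0233) called it, over a range of 0.0152 to 0.379. BAX rose by 0.76 (SE 0.0752, 1.691-fold, limma adjusted p = 2.64e-05). BCL2 fell by 0.33 (adjusted p = 0.0122), but its 4 probe sets ran from −0.33 to 0.14, and the call was lost without solvent array 2 (0.0507) or SGI-110 array 13 (0.0521), over a range of 0.000195 to 0.119. Among 5 inhibitor of apoptosis genes 0 rose and 0 fell (1 and 1 with the block, camera adjusted p = 0.734), with XIAP at 0.14 (limma adjusted p = 0.341) and BIRC2 at 0.18 (0.166, or 0.0354 with the block, range 0.00538 to 0.468). CASP8 (0.17, adjusted p = 0.246), CFLAR (0.11, 0.34) and BAK1 (−0.02, 0.899) did not pass either. MCL1 (0.22, adjusted p = 0.153), PMAIP1 (−0.22, 0.352) and BCL2L11 (0.20, 0.0639) did not pass but passed with the block (0.000944, 0.0121 and 0.0234), over ranges of 0.00029 to 0.643, 0.0038 to 0.764 and 0.00144 to 0.278.

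**Figure D2:**
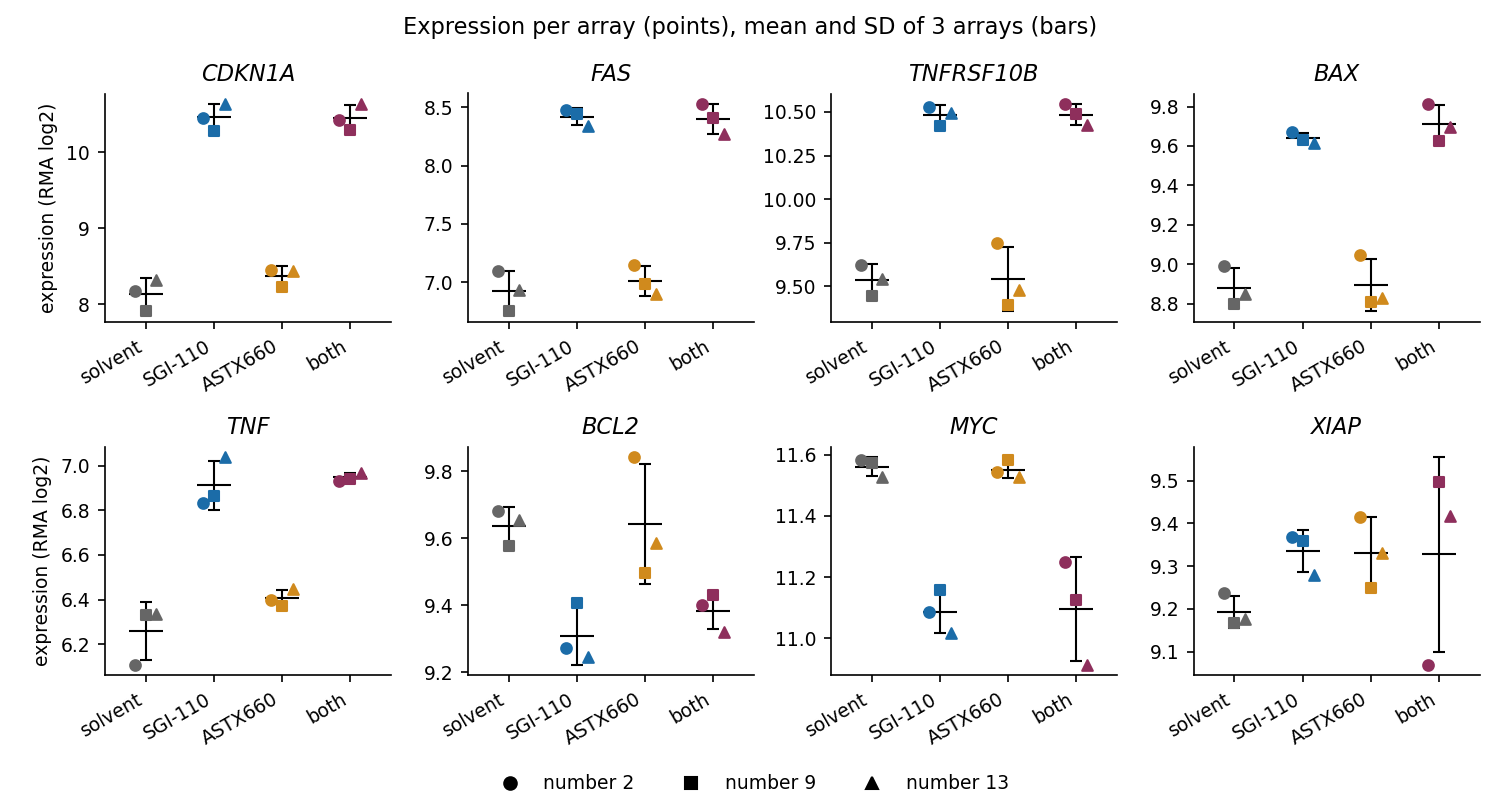
RMA log2 intensity (vertical axis) of 8 genes by treatment (horizontal axis), 1 point per array with the mean and SD of 3 arrays. CDKN1A, FAS, TNFRSF10B, BAX and TNF stood higher in both SGI-110 groups, FAS moving from 6.924 to 8.419 with SGI-110 alone.

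Genes of inflammation and antiviral defence rose with SGI-110. These included the NF-kB targets IER3 and CXCL8, the interferon-stimulated genes TRIM22, IFIT3, IRF7 and HERC5, the cancer-testis gene MAGEB2, the peptide transporter gene TAP1 and NLRC5, which controls class I antigen presentation. Of 27 NF-kB targets 10 rose, 1 fell and 16 did not pass (14 and 1 over the list alone, 15 and 2 with the block), with IER3 at 1.59 (3.01-fold, limma adjusted p = 2.74e-05) and CXCL8 at 0.79 (adjusted p = 0.00331). camera called the list higher (median 0.23, adjusted p = 0.000209, and adjusted p = 0.121 with an estimated correlation). Of 30 interferon-stimulated genes 12 rose, 0 fell and 18 did not pass (16 and 1 over the list alone, 16 and 1 with the block). TRIM22 rose by 1.11 (2.165-fold, limma adjusted p = 1.3e-05), IFIT3 by 0.85, IRF7 by 0.64 and HERC5 by 0.60, and the list was higher (median 0.22, camera adjusted p = 9.7e-06, and adjusted p = 0.121 with an estimated correlation). Only 6 of 50 cancer-testis genes were tested, since a gene needed a probe set with 1 symbol that was bright enough. Of these 3 rose and 0 fell, the same over the list alone, with TKTL1, MAEL and MAGEB2 (1.79, 3.463-fold, from a solvent mean of 4.09 that is also near background) rising (camera adjusted p = 0.00295, median 0.91, and adjusted p = 0.0735 with an estimated correlation). Without the brightness filter that median was 0.01 and camera gave 0.038, over a range of 1.25e-05 to 0.0735. The 3 genes that rose had solvent means below every array median, so their rise helped them pass the filter. The list test is therefore not independent of the change. Of 22 antigen presentation genes 7 rose and 0 fell, the same over the list alone (8 and 1 with the block): TAP1 rose by 0.62, NLRC5 by 0.50, HLA-B by 0.24 and HLA-C by 0.24, the HLA probes being able to read each other's transcripts (median 0.12, camera adjusted p = 0.00415, and adjusted p = 0.199 with an estimated correlation).

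Genes of mature myeloid cells rose with SGI-110 while mitotic, growth and amino acid stress genes fell. NCF1, encoding a subunit of the phagocyte oxidase, and MNDA, a nuclear antigen of myeloid cells, rose. The mitotic genes CCNB1, BUB1 and CKS2 fell, and so did MYC, its ribosome synthesis targets NOP16 and RRS1, the stress regulator gene ATF4 and the transporter gene SLC3A2. Of 20 myeloid maturation genes 11 rose, 0 fell and 9 did not pass (15 and 0 over the list alone), including NCF1 (1.32, 2.5-fold, with probes that can read its pseudogene copies) and MNDA (0.37). camera called the list higher (median 0.47, adjusted p = 3.51e-07, and adjusted p = 0.136 with an estimated correlation, or 0.0401 when the block was added). Of 35 G2/M genes 0 rose, 18 fell and 17 did not pass (0 and 22 over the list alone), with BUB1 falling by 0.44, CCNB1 by 0.42 and CKS2 by 0.35 (median −0.25, camera adjusted p = 1.4e-12, and adjusted p = 0.199 with an estimated correlation). Of 21 MYC and ribosome genes 0 rose and 14 fell (0 and 18 over the list alone): MYC fell by 0.47 (1.389-fold, limma adjusted p = 0.000355), NOP16 by 0.41 and RRS1 by 0.28 (median −0.24, camera adjusted p = 2.86e-10, and adjusted p = 0.0735 with an estimated correlation). Of 22 stress response genes 1 rose and 9 fell (1 and 12 over the list alone, 4 and 12 with the block), with ATF4 falling by 0.42 (limma adjusted p = 3.39e-05), SLC3A2 by 0.44 and XBP1 by 0.42 (median −0.21, camera adjusted p = 0.00129, and adjusted p = 0.166 with an estimated correlation, or 0.045 when the block was added).

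The remaining SGI-110 lists were not called by camera. CCND3 (0.58) and RRM2 (0.17) rose among 33 G1/S genes, of which 6 rose and 0 fell, the same over the list alone and 10 and 1 with the block (adjusted p = 0.193, or 0.0479 after quantile normalization and 0.0372 without SGI-110 array 2, range 0.0372 to 0.766). SRXN1 (0.48), MT2A (0.47) and MT1X (0.39) rose among 17 oxidative and heat stress genes, the metallothionein probes being able to read relatives. Of these 17 genes 6 rose and 0 fell, or 6 and 3 over the list alone and 7 and 4 with the block (camera adjusted p = 0.0804, or 0.0432 after quantile normalization, 0.0252 without solvent array 9 and 0.0334 without SGI-110 array 2, range 0.00161 to 0.234). Among 16 DNA methylation and decitabine genes 1 rose and 1 fell (3 and 2 with the block), with DCTD, a deoxycytidylate deaminase, falling by 0.31 (limma adjusted p = 0.00109; camera adjusted p = 0.577). DNMT1 (0.12, limma adjusted p = 0.0957, or 0.0305 with the block, range 0.00788 to 0.345), DNMT3A (0.15, 0.398) and DNMT3B (0.24, 0.102) did not pass. Counts higher and lower were 1 and 0 of 13 granule genes (3 and 2 with the block, camera adjusted p = 0.944), 0 and 0 of 9 HOXA programme genes (2 and 1 with the block, 0.944). They were 0 and 0 of 11 erythroid markers (0 and 1 with the block, 0.26), 2 and 0 of 14 lymphoid markers including NKG7 at 0.31 (0.794), and 1 and 0 of 13 fibroblast and epithelial markers (4 and 0 with the block, 0.185). Median and tested direction differed for the HOXA (median −0.00372, mean 0.0279, tested up), erythroid (0.00151, −0.0528, down) and lymphoid (−0.00905, 0.0662, up) lists. Of 10 called lists 7 were higher and 3 lower, 9 were lost with an estimated correlation (0.0735 to 0.199), and fry called 13.

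**Figure D3:**
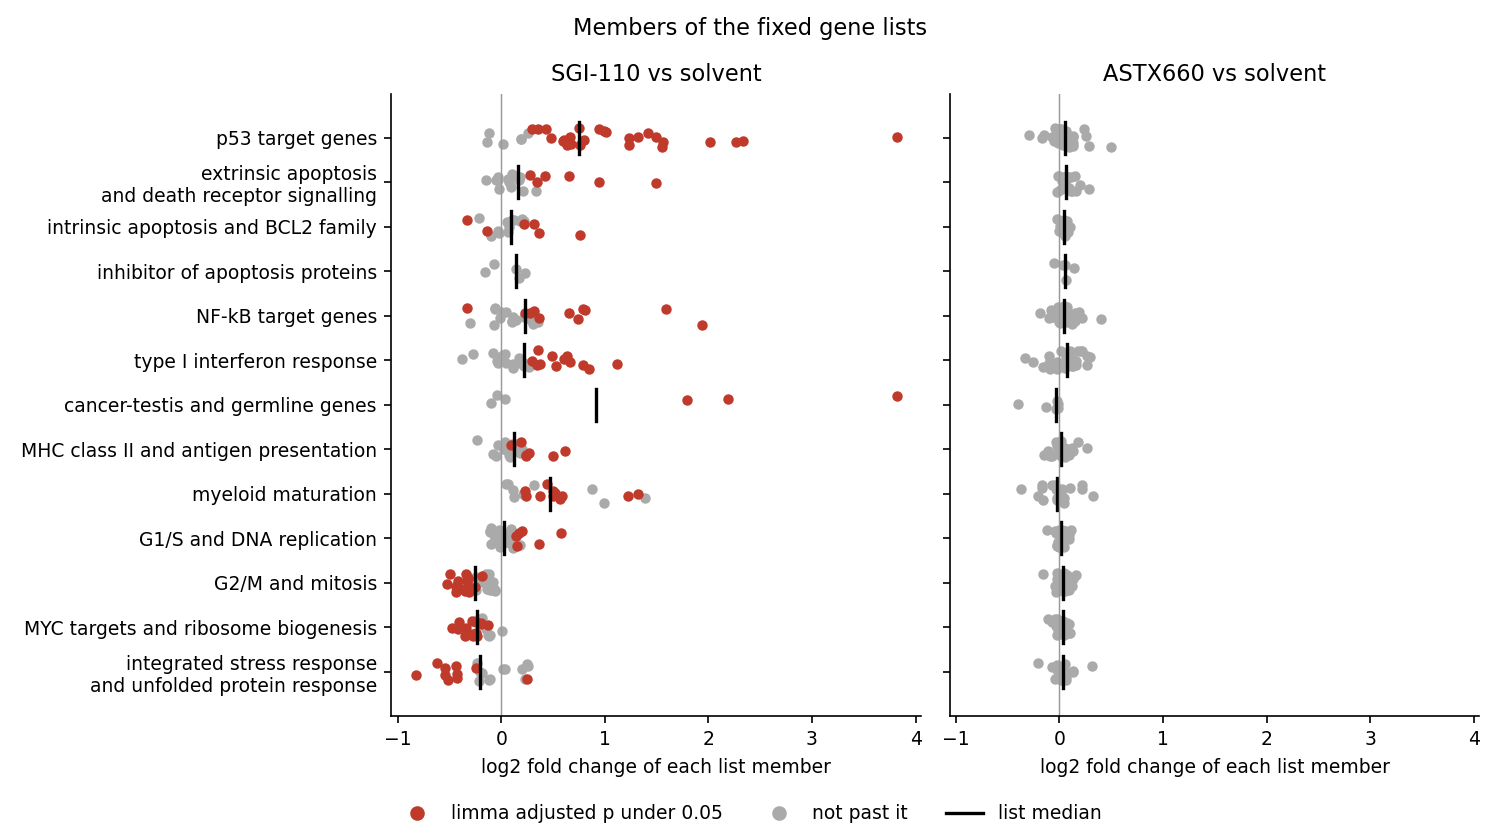
Change in log2 intensity (horizontal axis) of each tested member of 13 gene lists (vertical axis) for SGI-110 against solvent (left) and ASTX660 against solvent (right), 1 point per gene, red where the limma adjusted p was under 0.05, bars marking medians. The p53 targets stood at a median of 0.75 with SGI-110 and 0.05 with ASTX660.

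With ASTX660 alone no apoptosis gene passed the test. TNFSF10, TNF, FAS, TNFRSF10B, BAX, BCL2 and the genes XIAP and BIRC2, whose proteins it binds, were among them. CDKN1A and ACER2, a ceramidase gene among the p53 targets, did not pass. limma called 0 of 12689 genes, with 894 at an unadjusted p under 0.05 where 634 were expected and a smallest adjusted p of 0.632. Leaving out 1 array moved that count between 511 (ASTX660 array 2) and 1279 (ASTX660 array 9), with 540 without solvent array 9, and the block gave 1464. A robust fit and array weights also gave 0 calls (895 and 838 unadjusted), and arrays did not overlap in 12.3% of genes (10% by chance). Blocking gave 1 call, LSS of sterol synthesis (0.45, 1.37-fold, blocked adjusted p = 0.00765). The 95% interval lay within 1.5-fold for 97.8% of genes. FAS stood at 0.09 (adjusted p = 0.86), TNFRSF10B at 0.00 (0.995), BAX at 0.01 (0.974), BCL2 at 0.00 (0.993), TNF at 0.15 (0.729), TNFSF10 at 0.29 (0.701), XIAP at 0.14 (0.762), BIRC2 at 0.07 (0.867), CDKN1A at 0.24 (SE 0.116, 0.701) and ACER2 at 0.50 (SE 0.112, 0.632). Of the 20 lists fixed beforehand only marker lists of other lineages were called by camera, both lower with 0 members called: 11 erythroid markers such as TAL1 (−0.27) and EPOR (−0.23) at a median of −0.13 (adjusted p = 0.000101), and 14 lymphoid markers such as IKZF3 (−0.23) and PRF1 (−0.19) at −0.16 (adjusted p = 6.29e-05). Each was lost with an estimated correlation (adjusted p = 0.134 with an estimated correlation for both) and with fry (0.248), over ranges of 0.000126 to 0.248 and 1.49e-05 to 0.248. ASTX660 array 2 stood apart on component 3, and without it both stayed lower (camera adjusted p = 0.0197 each, medians −0.15 and −0.07). Other lists had camera adjusted p from 0.213 to 0.969, including p53 targets (32 tested, median 0.05, 1 higher over the list alone), extrinsic apoptosis (20, 0.06), intrinsic apoptosis (18, 0.05), inhibitor of apoptosis genes (5, 0.06), NF-kB targets (27, 0.04) and interferon-stimulated genes (30, 0.07). Median and tested direction differed for antigen presentation (median 0.0141, tested down) and MYC and ribosome genes (0.0319, down).

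The combination raised p53 targets and death receptor genes. TP53I3, TKTL1, CDKN1A, FAS, TNFRSF10B, BAX and TNF rose against solvent, and so did HTRA2, a mitochondrial protease that antagonises XIAP, and RIPK3, a kinase of necroptosis. AFF3, MANEAL, KATNAL2 and IMMP2L fell, as did MYC and ATF4. TP53I3 rose by 3.89 (14.8-fold, limma adjusted p = 4.59e-08), TKTL1 by 3.78 (13.76-fold, with the same solvent mean near background), MGST1 by 2.62, CDKN1A by 2.32 (SE 0.116, 4.993-fold, adjusted p = 4.59e-08) and MAEL by 2.27. AFF3 fell by 1.44 (2.711-fold), KATNAL2 by 1.18 and IMMP2L by 0.97, and MANEAL fell 2.384-fold. limma called 2275 genes, 1533 higher and 742 lower (67.4% higher), of which 110 changed at least 2-fold, 106 higher and 4 lower. Arrays did not overlap between groups in 2249 of these calls and in 38.4% of all genes (10% by chance). The split was 35.2% higher of 2953 calls after median centring and 54.1% of 2523 after quantile normalization. Blocking gave 3632 calls and leaving out solvent array 9 gave 1389.

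Of 32 p53 targets 27 rose with the combination and 1 fell, with 27 higher over the list alone (median 0.81, camera adjusted p = 2.41e-25, and adjusted p = 0.0317 with an estimated correlation, the only list so kept). Of 20 extrinsic apoptosis genes 7 rose and 0 fell (9 and 0 over the list alone, 10 and 1 with the block): FAS by 1.48 (SE 0.0972, 2.786-fold, limma adjusted p = 6.07e-07), TNFRSF10B by 0.95 (SE 0.0795, 1.931-fold, adjusted p = 6.07e-06), TNF by 0.69 (adjusted p = 9.12e-05) and RIPK3 by 0.40 (adjusted p = 0.00301). TNFSF10 rose by 0.52 (adjusted p = 0.0109), a call lost without solvent array 9 (0.052, range 0.000515 to 0.0583). camera called that list higher (median 0.19, adjusted p = 0.000144, and adjusted p = 0.208 with an estimated correlation). Of 18 intrinsic apoptosis genes 5 rose and 2 fell (9 and 3 over the list alone, 9 and 4 with the block), BAX by 0.83 (SE 0.0752, 1.779-fold, limma adjusted p = 1.19e-05), HTRA2 by 0.35 (0.0023) and APAF1 by 0.43 (0.00858). The intrinsic list was called narrowly (median 0.13, camera adjusted p = 0.0485, and adjusted p = 0.275 with an estimated correlation, range 0.00309 to 0.275). It was lost without solvent array 2 (0.067), solvent array 9 (0.0619), combination array 13 (0.0656) or combination array 9 (0.0745), and with the block (0.0621). BCL2 fell by 0.25 (limma adjusted p = 0.0398), a call lost on leaving out each of the 6 arrays compared (0.0562 to 0.126, range over all alternatives 0.00151 to 0.215). The same held for BCL2L11, a BH3-only gene that rose by 0.21 (adjusted p = 0.0484, 0.0795 to 0.128 on leaving out an array, range 0.000962 to 0.48). Of 5 inhibitor of apoptosis genes 1 rose and 0 fell (1 and 1 with the block, camera adjusted p = 0.599), with XIAP at 0.13 (limma adjusted p = 0.323, or 0.019 without combination array 2, range 0.019 to 0.749) and BIRC2 at 0.14 (0.238) not passing. CASP8 (0.19, adjusted p = 0.155), CFLAR (0.18, 0.0742, or 0.0192 with the block, range 0.00784 to 0.279), MCL1 (0.24, 0.101, or 0.000378 with the block, range 0.000117 to 0.63) and PMAIP1 (−0.20, 0.338, or 0.0168 with the block, range 0.00551 to 0.758) did not pass.

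Inflammatory, interferon and myeloid genes also rose with the combination, and mitotic and growth genes fell. Of 27 NF-kB targets 11 rose and 0 fell (16 and 2 over the list alone, 18 and 2 with the block), among them IER3 (1.58) and TNFAIP3 (0.40), at a median of 0.23 (camera adjusted p = 0.000136, and adjusted p = 0.139 with an estimated correlation). Of 30 interferon-stimulated genes 17 rose and 1 fell (17 and 2 over the list alone, 17 and 2 with the block), among them TRIM22 (1.12), IFIT3 (1.02) and IRF7 (0.76), at a median of 0.31 (camera adjusted p = 1.59e-05, and adjusted p = 0.139 with an estimated correlation). Of 20 myeloid maturation genes 13 rose and 0 fell (16 and 1 over the list alone, 17 and 1 with the block), among them NCF1 (1.27), CSF1R (0.76) and CYBB (0.70), at a median of 0.42 (camera adjusted p = 4.37e-06, and adjusted p = 0.19 with an estimated correlation). Of 35 G2/M genes 14 fell and 0 rose (21 and 0 over the list alone, 23 and 0 with the block), among them HMMR (−0.47) and BUB1 (−0.38), at −0.23 (camera adjusted p = 9.85e-09, and adjusted p = 0.275 with an estimated correlation). Of 21 MYC and ribosome genes 14 fell and 0 rose (18 and 0 over the list alone), among them MYC (−0.47) and NOP16 (−0.38), at −0.24 (camera adjusted p = 7.75e-09, and adjusted p = 0.114 with an estimated correlation). Of 22 stress response genes 7 fell and 1 rose (8 and 1 over the list alone, 11 and 3 with the block), with ATF4 falling by 0.39 and SLC3A2 by 0.39 while EDEM1 rose by 0.32 (median −0.17, camera adjusted p = 0.00477, and adjusted p = 0.208 with an estimated correlation).

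Cancer-testis and oxidative stress genes gave narrower list calls with the combination. TKTL1, MAEL and MAGEB2 (1.57) rose among 6 cancer-testis genes, 3 higher and 0 lower (3 and 1 over the list alone), at a median of 0.82 (camera adjusted p = 0.0294, and adjusted p = 0.139 with an estimated correlation, range 1.76e-05 to 0.171). That call was lost with the block (0.057), without ASTX660 array 2 (0.0579) and without the brightness filter (0.171, median −0.0052). As with SGI-110 alone, the rise of these 3 genes helped them pass that filter. MT2A (0.46), SRXN1 (0.38) and NQO1 (0.38) rose among 17 oxidative and heat stress genes, 5 higher and 0 lower (7 and 0 over the list alone, 8 and 0 with the block), at a median of 0.24 (camera adjusted p = 0.0476, and adjusted p = 0.208 with an estimated correlation, range 0.000738 to 0.208). That call was lost without solvent array 13 (0.076), solvent array 2 (0.0581), combination array 9 (0.0745) or ASTX660 array 2 (0.0676). TAP1 (0.66), NLRC5 (0.49) and HLA-B (0.22) were among 7 higher and 0 lower of 22 antigen presentation genes (9 and 1 with the block), whose list did not pass (camera adjusted p = 0.0579, or 0.032 without solvent array 13 and 0.0191 without combination array 9, range 0.0125 to 0.365). The 11 called lists, 8 higher and 3 lower, became 12 with fry, and 10 were lost with an estimated correlation (0.114 to 0.275). DCTD (−0.28) fell among 16 DNA methylation and decitabine genes, 3 higher and 1 lower (6 and 3 with the block, camera adjusted p = 0.698), while DNMT1 (0.11, limma adjusted p = 0.0988, or 0.0353 with the block, range 0.00981 to 0.601) and DNMT3A (0.26, 0.0911, or 0.0278 with the block, range 0.0106 to 0.38) did not pass. DNMT3B rose by 0.31 (limma adjusted p = 0.0324), a call lost without solvent array 9 (0.147), combination array 13 (0.0956) or combination array 9 (0.0863), and after median centring (0.0644) or quantile normalization (0.0519), range 0.00861 to 0.147. Counts higher and lower in the other lists were 6 and 1 of 33 G1/S genes (8 and 3 with the block, camera adjusted p = 0.628), 1 and 0 of 13 granule genes (3 and 2 with the block, 0.988), 1 and 0 of 9 HOXA programme genes (2 and 0 with the block, 0.836). Among markers of other lineages they were 0 and 0 of 11 erythroid markers (0 and 1 with the block, 0.0597, or 0.044 without solvent array 13 and 0.0378 without combination array 2, range 0.0378 to 0.275), 2 and 1 of 14 lymphoid markers (0.483), and 2 and 0 of 13 fibroblast and epithelial markers (5 and 2 with the block, 0.717).

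With ASTX660 added after SGI-110 no apoptosis gene passed the test. FAS, TNFRSF10B, TNFSF10, TNF, BAX, CDKN1A, XIAP and BIRC2 did not pass, nor did MX1, an interferon-induced antiviral gene, FPR1, a receptor of mature myeloid cells, or the kinase gene MAP3K8. limma called 0 genes, with 370 at an unadjusted p under 0.05 against 634 expected, a smallest adjusted p of 0.689, and 98.8% of genes having a 95% interval within 1.5-fold. The unadjusted count was 210 without SGI-110 array 2 and 590 with the block. The fit without the block left differences between experiment numbers in its error, which can lower the count. With the block the count was still below 634, so those differences do not account for the whole shortfall. A count below the expected one is not by itself evidence that nothing changed. A robust fit and array weights also gave 0 (361 and 626 unadjusted), and arrays did not overlap in 8.69% of genes (10% by chance). Blocking gave 10 calls, all higher by 1.181-fold to 1.358-fold and mostly enzymes of sterol synthesis: MSMO1 (0.44, blocked adjusted p = 0.00309), IDI1 (0.31, 0.0201), INSIG1 (0.30, 0.0201), FDPS (0.27, 0.0201), EBP (0.26, 0.0201), SQLE (0.24, 0.0369), LSS (0.33, 0.0391), ACAT2 (0.29, 0.0391), the fatty acid desaturase gene SCD (0.36, 0.0299) and the tubulin gene TUBA1A (0.27, 0.0201). Without the block their adjusted p was 0.689 for IDI1 and 1 for the others. Differences were −0.02 for FAS, 0.00 for TNFRSF10B, 0.07 for BAX, 0.04 for TNF, 0.09 for TNFSF10, −0.01 for CDKN1A, −0.01 for XIAP and −0.03 for BIRC2, and each had a limma adjusted p of 1. MX1 (−0.37), FPR1 (−0.37) and MAP3K8 (0.41) did not pass. Of the 20 lists only the 14 lymphoid markers were called, lower at a median of −0.06 with 0 members called (camera adjusted p = 0.0431, and adjusted p = 0.711 with an estimated correlation, range 0.0057 to 0.841). That call was lost without combination array 2 (0.0505), combination array 9 (0.192), SGI-110 array 2 (0.268) or SGI-110 array 9 (0.122), and fry gave 0.841. The 35 G2/M genes had a median of 0.06 with 33 positive and were not called (camera adjusted p = 0.0786, and 0.917 with an estimated correlation, range 9.72e-05 to 0.987). They were called with the block (0.0142) and without combination array 9 (9.72e-05), SGI-110 array 13 (0.00533) or SGI-110 array 2 (0.0263). Leaving out 1 array also called G1/S genes (without combination array 9, 0.000923, or SGI-110 array 2, 0.0063, range 0.000923 to 0.987), myeloid maturation (without combination array 9, 0.0129, range 0.0129 to 0.964). It called antigen presentation and fibroblast and epithelial markers as well (without combination array 13, 0.0374 each, ranges up to 0.969 and 0.841) and erythroid markers (without SGI-110 array 13, 0.0416, range 0.0416 to 0.941). Median and tested direction differed for myeloid maturation (median 0.0298, tested down), and for DNA methylation genes only the mean differed (0.00446, median −0.0023, tested down).

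Against ASTX660 alone the combination raised p53 targets, death receptor genes and the germline genes TKTL1, MAEL and MAGEB2. TKTL1, TP53I3, CDKN1A, FAS, TNFRSF10B, BAX and TNF rose, as did MYO5C, a myosin gene, and CSF1R, the receptor of a macrophage growth factor. AFF3, MANEAL, KATNAL2, IMMP2L and GRB10, an adaptor gene of growth factor signalling, fell. TKTL1 rose by 4.18 (limma adjusted p = 1.83e-07, from an ASTX660 mean of 3.80 below every array median, so that its fold is not exact). TP53I3 rose by 3.75, MAEL by 2.29, CDKN1A by 2.08 (SE 0.116, 4.227-fold, adjusted p = 1.71e-07), MYO5C by 1.93 (3.808-fold), FAS by 1.39 (SE 0.0972, 2.624-fold, adjusted p = 1.06e-06), TNFRSF10B by 0.95 (1.927-fold, adjusted p = 7.3e-06), BAX by 0.82 (1.762-fold, adjusted p = 1.7e-05) and TNF by 0.54 (adjusted p = 0.00059). AFF3 fell by 1.55 (2.931-fold), MANEAL by 1.29, KATNAL2 by 1.26, IMMP2L by 1.03 and GRB10 by 0.92. limma called 2038 genes, 1062 higher and 976 lower (52.1% higher), of which 82 changed at least 2-fold, 77 higher and 5 lower. Arrays did not overlap between groups in 1992 of these calls and in 29.4% of all genes (10% by chance). Leaving out combination array 2 or 13 gave 1310 or 1313 calls. Without ASTX660 array 2 there were 1992 calls, 62.6% higher.

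Extrinsic apoptosis, p53, inflammatory and myeloid lists were higher and mitotic and growth lists lower. Of 32 p53 targets 27 rose and 0 fell (median 0.71, camera adjusted p = 8.5e-31, and adjusted p = 0.0171 with an estimated correlation, the only list so kept). Of 20 extrinsic apoptosis genes 5 rose and 0 fell (0.10, camera adjusted p = 0.00274, and adjusted p = 0.274 with an estimated correlation), and of 27 NF-kB targets such as IER3 (1.58) and CXCL8 (0.81) 8 rose and 1 fell, or 11 and 1 over the list alone (0.16, 0.000119, and adjusted p = 0.119 with an estimated correlation). Of 30 interferon-stimulated genes such as TRIM22 (1.06) and IRF7 (0.63) 12 rose and 0 fell, or 13 and 1 over the list alone (0.20, camera adjusted p = 5.98e-05, and adjusted p = 0.12 with an estimated correlation). Cancer-testis genes had 3 of 6 higher, TKTL1, MAEL and MAGEB2, the last at 3.037-fold (0.84, 0.00274, and adjusted p = 0.0767 with an estimated correlation). All 3 were near background without SGI-110, so their rise helped them pass the brightness filter, and their folds are not exact. Their list test is therefore not independent of the change. Myeloid maturation had 11 of 20 higher, or 13 over the list alone, with NCF1 at 1.34, CSF1R at 0.97 and FGR at 0.75 (0.42, camera adjusted p = 2.57e-08, and adjusted p = 0.119 with an estimated correlation). Antigen presentation had 6 of 22 higher, or 7 over the list alone, with TAP1 at 0.49 and HLA-E at 0.32 (0.11, camera adjusted p = 0.0172, and adjusted p = 0.274 with an estimated correlation, range 0.00399 to 0.274), and was lost without ASTX660 array 9 (0.0736) or combination array 13 (0.139). G2/M genes such as BUB1 (−0.43) and CKS2 (−0.35) had 18 of 35 lower, or 24 over the list alone (−0.25, camera adjusted p = 6.47e-10, and adjusted p = 0.274 with an estimated correlation). MYC (−0.46) and NOP16 (−0.40) were among 16 of 21 lower MYC and ribosome genes, or 18 over the list alone (−0.22, camera adjusted p = 5.52e-09, and adjusted p = 0.0767 with an estimated correlation). ATF4 (−0.40) and SLC3A2 (−0.38) were among 9 lower and 1 higher of 22 stress response genes, or 13 and 1 over the list alone (−0.21, camera adjusted p = 0.00274, and adjusted p = 0.198 with an estimated correlation).

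MT2A (0.47) and MT1X (0.35) rose against ASTX660 among 17 oxidative and heat stress genes, 6 higher and 3 lower (camera adjusted p = 0.0778, or 0.0455 without ASTX660 array 13, range 0.00577 to 0.274). BAX rose among 18 intrinsic apoptosis genes, 3 higher and 3 lower (0.138, or 0.031 without the brightness filter and 0.0297 with fry, range 0.0297 to 0.394), and DCTD (−0.34) fell among 16 DNA methylation and decitabine genes, 2 higher and 1 lower (0.878). DNMT3A rose by 0.33 (limma adjusted p = 0.0432), a call lost without ASTX660 array 9 (0.167) or combination array 13 (0.103), 2 (0.121) or 9 (0.0629), range 0.00173 to 0.231. BCL2 fell by 0.26 (limma adjusted p = 0.0403), a call lost without ASTX660 array 2 (0.116) or 13 (0.0524) or combination array 13 (0.131), 2 (0.0856) or 9 (0.0545), range 0.00943 to 0.155. XIAP (0.00, adjusted p = 0.985), BIRC2 (0.07, 0.587), CASP8 (0.08, 0.626), CFLAR (0.12, 0.266), BAK1 (0.01, 0.965), BCL2L11 (0.13, 0.219) and TNFSF10 (0.23, 0.243) did not pass. Counts higher and lower were 4 and 2 of 33 G1/S genes (camera adjusted p = 0.693), 1 and 0 of 5 inhibitor of apoptosis genes (0.791), 1 and 0 of 13 granule genes (0.513), 1 and 0 of 9 HOXA programme genes (0.876). Marker counts were 0 and 0 of 11 erythroid markers (0.791), 2 and 0 of 14 lymphoid markers (0.138, or 0.026 without ASTX660 array 9, range 0.026 to 0.871) and 3 and 0 of 13 fibroblast and epithelial markers (0.31, or 0.0329 with the mean of all probe sets, range 0.0329 to 0.791). Of 10 called lists 7 were higher and 3 lower, 9 were lost with an estimated correlation (0.0767 to 0.274), and fry called 12. Median and tested direction differed for inhibitor of apoptosis genes (median −0.00371, tested up), erythroid markers (−0.000111, up) and fibroblast and epithelial markers (−0.014, up). Only the mean differed for DNA methylation (mean −0.00147, median 0.0152, tested up) and HOXA genes (0.01, −0.0182, down).

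Departure from additivity was tested as the interaction. FAS, TNFRSF10B, TNF, BAX, CDKN1A, XIAP and BIRC2 did not pass, nor did ACER2, CSF1R or the antiviral gene OAS2. limma called 0 genes with and without the block, with 204 at an unadjusted p under 0.05 against 634 expected and a smallest adjusted p of 0.644. A robust fit and array weights also gave 0 (201 and 333 unadjusted), and 322 were under 0.05 unadjusted without ASTX660 array 13 and 394 with the block. Here too the fit without the block kept differences between numbers in its error, which can lower the count. With the block the count was still below 634, so those differences do not account for the whole shortfall. The low count by itself is not evidence of additivity. The interaction was −0.10 for FAS (SE 0.137), −0.25 for CDKN1A (SE 0.165), −0.11 for TNF, 0.00 for TNFRSF10B, 0.06 for BAX, −0.15 for XIAP, −0.10 for BIRC2, −0.44 for ACER2 (SE 0.159), 0.45 for CSF1R and 0.45 for OAS2. The 95% interval lay within 1.5-fold for 92.7% of genes. The planted test recovered 58% of 1.5-fold interactions, but stronger ones were planted beside them, which eases the threshold. camera called 0 lists, the smallest adjusted p being 0.0965 for erythroid markers, with 0.952 to 0.972 for all lists with an estimated correlation. Single arrays left out called erythroid markers (without SGI-110 array 2, 0.00111, combination array 9, 0.0156, ASTX660 array 9, 0.0179, or solvent array 13, 0.0464, range 0.00111 to 0.973), lymphoid markers (without ASTX660 array 9, 0.0179, SGI-110 array 2, 0.0243, or combination array 9, 0.0456, range 0.0179 to 0.973). They also called G2/M genes (without solvent array 9, 0.000766, or combination array 9, 0.0142, range 0.000766 to 0.994), G1/S genes (without combination array 9, 0.0142, or SGI-110 array 2, 0.0386, range 0.0142 to 0.995) and myeloid maturation (without combination array 9, 0.00702, range 0.00702 to 0.996). Median and tested direction differed for the HOXA list (median 0.00109, tested down) and intrinsic apoptosis (−0.0199, up). The mean differed from the tested rise for inhibitor of apoptosis genes (−0.00916), NF-kB targets (−0.0106), stress response genes (−0.00597) and MYC and ribosome genes (−0.00482).

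CDKN1A, FAS and TP53I3 were among the genes that SGI-110 raised both without and with ASTX660. Taking SGI-110 against solvent and the combination against ASTX660, which share no arrays, 867 genes were higher in both (101 expected), 590 lower in both (57.6 expected) and 0 opposite. Across genes the changes correlated at 0.889 (rank correlation 0.763), and of 2536 genes called in either comparison 99.1% had the same sign. For ASTX660 without and with SGI-110 the correlation was 0.382 (rank correlation 0.364), or 0.194 without ASTX660 array 2. The dimmest genes (quartile 1 of mean level) tended lower with ASTX660 in both comparisons. Their median deviations per array were −0.0811 to 0.0169 with ASTX660 and 0.00884 to 0.0465 with solvent. With the combination they were −0.0449 to −0.000713, and with SGI-110 −0.00729 to 0.0612. A brightness-dependent shift shared by both comparisons could add to this correlation, and its part was not tested. Genes are not independent replicates, so these correlations carry no p.

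**Figure D4:**
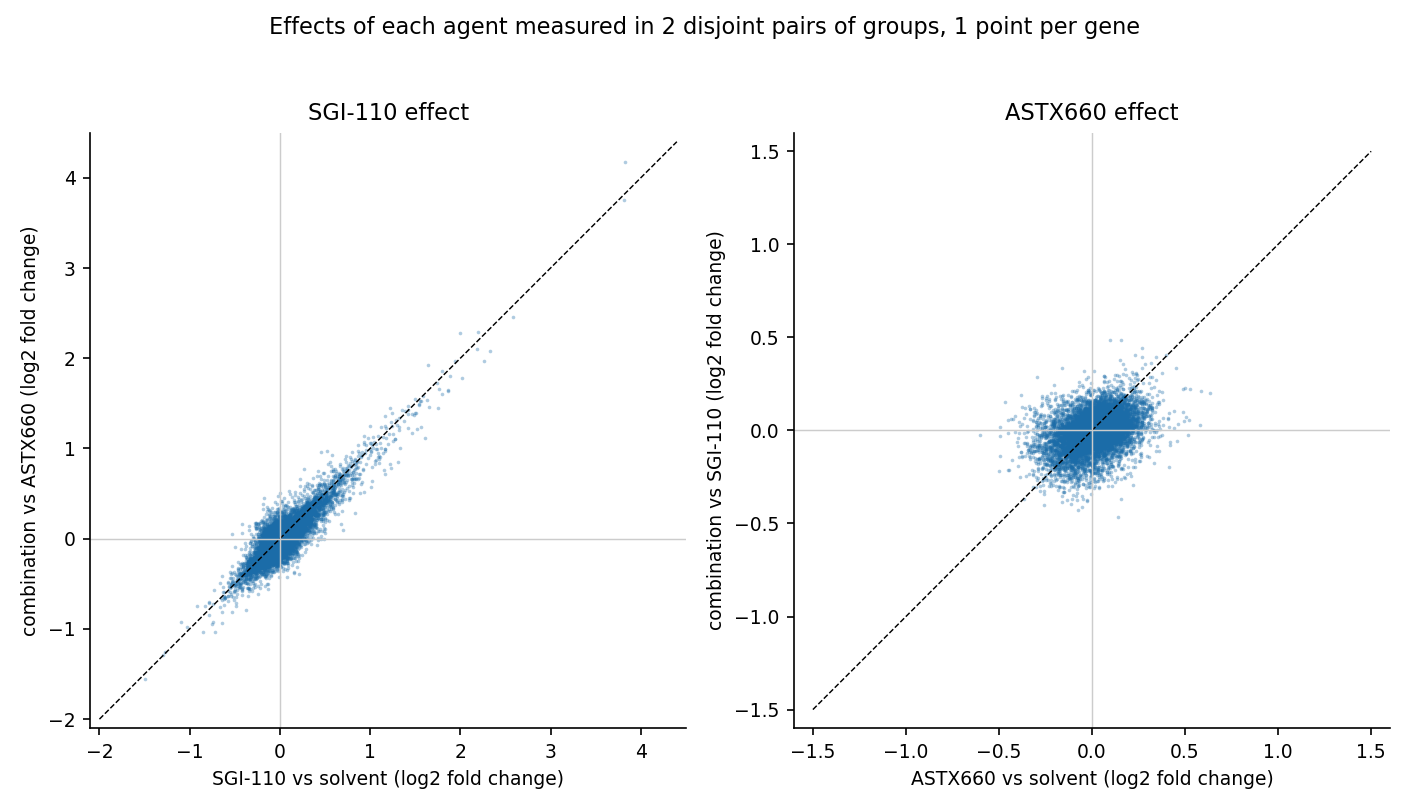
Left: log2 change of SGI-110 against solvent (horizontal) and of the combination against ASTX660 (vertical). Right: ASTX660 against solvent and the combination against SGI-110, 1 point per gene with a dashed line of equality, the correlations being 0.889 and 0.382.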

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

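Chosen only after the result was seen were the tests of the cholesterol genes for 1 deviating array and for a difference between experiments, the test of the dimmer genes for the floor of the scale, and the cholesterol list itself.

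Cholesterol synthesis genes, a list added after the data were seen, stood higher with ASTX660: of 21 tested members 19 were positive against solvent (median 0.23, camera adjusted p = 9.64e-11 over the 5 added lists, and adjusted p = 0.0815 with an estimated correlation) and 19 against SGI-110 alone (0.28, 6.02e-22, and 0.011 with an estimated correlation, or 0.0663 over all 30 tests of added lists). Against solvent LSS stood at 0.45, ACAT2 at 0.32 and SQLE at 0.23, and 0 members passed limma over all genes in either comparison (1 and 8 with the block), while 12 and 15 members passed over the list alone. SGI-110 alone lowered this list (median −0.13, camera adjusted p = 0.000531, and 0.15 with an estimated correlation). The difference against SGI-110 thus started from a lowered level. Against solvent the combination was not called (median 0.07, camera adjusted p = 0.135, 4 members higher and 0 lower). The tables argue against a brightness-dependent shift (0 of 10000 expression-matched random lists had a median as high in either comparison, a share of 1e-04). The list was chosen after such genes were seen to be high, so that share overstates how rare its shift is. The tables also argue against ASTX660 array 2 as the whole cause, since the median against solvent was 0.21 without it. Other arrays were not left out in this test. The combination against SGI-110 does not use that array, but 8 members were called there with the block. Those calls prompted the list, so that comparison is no separate support. The list median was higher in 6 of 6 number-matched pairs, by 0.155 to 0.311, and by 0.133 to 0.33 among the 13 members that the blocked fit did not call. That fit prompted the list and calls genes whose number-matched differences agree, and the 13 members were added as genes of the same pathway. The pairs therefore cannot decide about a difference between experiments. A rise of sterol synthesis transcripts with ASTX660 is a hypothesis found and tested on the same arrays, and other technical causes that follow ASTX660 treatment itself were not tested.

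Erythroid and lymphoid marker lists stood lower with ASTX660 at medians of −0.13 and −0.16, with 0 members called. The tables argue against a brightness-dependent shift for the markers of both lists pooled (share of expression-matched lists as low 1e-04, and 0.017 and 0.0015 for the lists alone) and against 1 deviating array as the whole cause, since 2 of 2 lists passed without ASTX660 array 2 (camera adjusted p = 0.0197 each). Without it the erythroid median was −0.151, but the lymphoid median went from −0.156 to −0.0733, so a large part of the lymphoid shift rested on that array. The markers were dim, with median levels of 4.97 and 5.42 against 7.7 for all tested genes, and the calls were lost with an estimated correlation (camera adjusted p = 0.134 each), so cross-hybridisation of dim probe sets stays open and was not tested. No contribution of other cells was tested, the samples being 1 cell line.

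Of the genes changed at least 2-fold by SGI-110, 96 of 100 were higher. Among genes above the middle of mean level this was 24 of 24 (100%, 95% interval 85.8 to 100, which treats genes as independent). The mean level took in the SGI-110-treated arrays, so a rise moved a gene towards the brighter genes and a fall towards the dimmer ones. This split therefore cannot decide about the floor of the scale among the brighter genes. Among the dimmer genes 72 of 76 were higher. Of called genes of any fold 79.3% were higher among the dimmer genes (560 of 706) against 51.7% among the brighter genes (646 of 1249). The floor of the scale and a change in the cells therefore cannot be told apart for dim genes either. Removal of methylation by SGI-110 is the difference the design names, and it stays untested because methylation was not used here.

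The real grouping of 6 arrays was compared with all 10 splits into 3 and 3. For SGI-110 against solvent 1 of 10 splits, the real one, gave as many calls (1955, highest other 0), for the combination against solvent 1 of 10 (2275, highest other 0) and for the combination against ASTX660 1 of 10 (2038, highest other 0). For ASTX660 against solvent 10 of 10 splits and for the combination against SGI-110 10 of 10 gave the real count of 0. These splits are too few for a share under 0.05. Where the real split gave calls, every other split mixed the treatments within its groups. The treatment change then enters the error and lowers the count, so the highest other count of 0 is no separate support. For the interaction all 100 drawn assignments gave at least the real count of 0, the highest other being 14. No count can lie below 0, so this outcome was fixed in advance and decides nothing. The same holds for ASTX660 against solvent and for the combination against SGI-110.

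Probe sets outside the gene analysis also carried signal with SGI-110. Of 1145 tested probe sets with several gene symbols 133 passed the limma threshold, 67 higher and 66 lower (11.6%). Of 3503 tested probe sets with no gene listed 128 passed, 83 higher and 45 lower (3.65%), against 2677 of 23660 probe sets with 1 symbol (11.3%).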

How the results depend on the processing

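Chosen only after the result was seen were the fits without the arrays numbered 13, with the block and without ASTX660 array 2, and without that array where the comparison does not use it. Calls for SGI-110 against solvent (1955) were 3202 with the replicate block, 1046 without number 13, 3901 with the block and without ASTX660 array 2, 899 at an adjusted p under 0.01, 100 at 2-fold or more, and 1239 to 2312 leaving out 1 array. For the combination against solvent (2275) the same settings gave 3632, 1305, 4420, 1101, 110 and 1389 to 2751. For the combination against ASTX660 (2038) they gave 3378, 1054, 3474, 894, 82 and 1310 to 1992, and 1232 with only the groups compared. There the numbers did not pair the arrays (correlations 0.057, 0.158 and 0.539, and only number 13 matched its own best). For ASTX660 against solvent (0) the block gave 1 call, and 1 without ASTX660 array 2, and for the combination against SGI-110 (0) it gave 10 and 16. The interaction stayed at 0 in every setting. The correlation of ASTX660 changes with and without SGI-110 went from 0.382 to 0.194 without ASTX660 array 2. The cause of these moves was not tested beyond fewer arrays, fewer genes or stricter thresholds by construction.

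Other filters, probe set choices, scalings, variance models and weights gave 1534 to 2812, 1876 to 2953 and 1769 to 2278 calls for these 3 comparisons. No named gene changed direction past the threshold. Among the 20 lists fixed beforehand, beyond the values given beside the results, the block changed only the oxidative and heat stress list for the combination against ASTX660 (0.0487). Of the added lists it called fatty acid synthesis for that comparison (camera adjusted p = 0.0502, 0.0276 with the block), and it added calls of some of their members. With an estimated correlation that list did not pass (camera adjusted p = 0.21, or 0.197 with the block). The p53 targets kept their call with an estimated correlation in all 3. For the combination against solvent, intrinsic apoptosis was also lost with quantile normalization (0.05), the mean of all probe sets (0.158) and without number 13 (0.0677), and oxidative stress with median centring (0.0506) and the mean of all probe sets (0.0629). For the combination against SGI-110, the lymphoid list was lost with quantile normalization (0.206) and median centring (0.068). For the combination against ASTX660, antigen presentation was lost without number 13 (0.0631). Fibroblast and epithelial markers were called for SGI-110 with the mean of all probe sets (0.0253), fry (0.0232) and without number 13 (0.022). Among genes, the mean of all probe sets ended the SGI-110 call of BCL2 (0.11). With 3 arrays per group, small changes were often missed, and only 12689 of 19775 genes were bright enough to test.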

Other observations

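Chosen only after the result was seen were the 4 lists described here and the genes named with them.

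Ligands that NK and T cells read rose with SGI-110, as did lysosome genes. TNFSF9, CD70 and TNFSF4, costimulatory ligands of the TNF family, CD86, the checkpoint gene VSIR and the NKG2D ligand gene ULBP2 rose, and so did the cathepsin genes CTSB and CTSD, the sialidase gene NEU1, the proton pump subunit gene ATP6V0D1 and the autophagy receptor gene SQSTM1. Of 15 tested ligand genes 8 rose and 0 fell, the same over the list alone, with TNFSF9 at 1.47, CD86 at 1.23, CD70 at 0.67, TNFSF4 at 0.54, VSIR at 0.54 and ULBP2 at 0.44 (median 0.19, camera adjusted p = 0.000219 over the 5 added lists, and adjusted p = 0.0407 with an estimated correlation, or 0.0813 over all 30 tests). Of 23 lysosome and autophagy genes 12 rose and 0 fell, the same over the list alone, with NEU1 at 0.64, CTSB at 0.56, ATP6V0D1 at 0.42, CTSD at 0.40 and SQSTM1 at 0.30 (median 0.24, camera adjusted p = 9.04e-08, and adjusted p = 0.0407 with an estimated correlation, 0.0813 over all 30 tests, or 0.072 when the block was added). In the other SGI-110-treated comparisons both lists were higher by camera but lost the call with an estimated correlation. Against solvent the combination gave camera adjusted p = 0.00427 and 1.49e-08 for the ligand and lysosome lists (adjusted p = 0.0601 with an estimated correlation for both). Against ASTX660 it gave 0.000874 and 3.99e-08 (adjusted p = 0.0545 with an estimated correlation for both). For the combination against SGI-110 camera called the lysosome list higher with 0 members called (median 0.0344, adjusted p = 0.036). That call was lost with an estimated correlation (0.466) and quantile normalization (0.05), and the median was −0.00378 after median centring.

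Amino acid transport genes fell with SGI-110, and so did some lipid synthesis genes. SLC7A5, which with SLC3A2 imports leucine, BCAT1, SHMT2 and MTHFD2 of mitochondrial folate metabolism, and the sterol and fatty acid genes HMGCS1, INSIG1, SCD and FASN were lower. Of 19 amino acid genes 0 rose and 11 fell (0 and 13 over the list alone), with BCAT1 at −0.79, SLC7A5 at −0.65, SLC3A2 at −0.44 and SHMT2 at −0.39 (median −0.34, camera adjusted p = 1.1e-07, and adjusted p = 0.0407 with an estimated correlation, 0.0813 over all 30 tests, or 0.0526 when the block was added). The amino acid list was lower by camera in the other SGI-110-treated comparisons too, but not with an estimated correlation (combination against solvent, camera adjusted p = 2.85e-06, and adjusted p = 0.0601 with an estimated correlation; combination against ASTX660, 1.53e-06 and 0.0545). Of 21 cholesterol genes 0 rose and 6 fell (1 and 8 over the list alone), with HMGCS1 at −0.53, MSMO1 at −0.38, TMEM97 at −0.38 and INSIG1 at −0.36 (median −0.13, camera adjusted p = 0.000531, and adjusted p = 0.15 with an estimated correlation). Of 14 fatty acid genes 1 rose and 5 fell (2 and 5 over the list alone, 2 and 6 with the block), with SCD at −0.56, ACACA at −0.43, FASN at −0.33 and ACLY at −0.24 lower and ACSL1 at 0.30 higher (median −0.13, camera adjusted p = 0.0166, and adjusted p = 0.126 with an estimated correlation). Against ASTX660 the combination had 4 cholesterol genes lower, TMEM97, LSS, HMGCS1 and INSIG1, and 0 higher. That list was lower (median −0.12, camera adjusted p = 0.0138, and adjusted p = 0.285 with an estimated correlation). In the same comparison 3 fatty acid genes, SCD, ACLY and ACACA, were lower and 0 higher, and their list did not pass (median −0.10, camera adjusted p = 0.0502). With the combination against solvent the lipid lists did not pass: 4 cholesterol genes rose and 0 fell (5 and 0 over the list alone, 6 and 1 with the block, median 0.07, camera adjusted p = 0.135), and 2 fatty acid genes rose and 0 fell (2 and 3 over the list alone, median −0.02, camera adjusted p = 0.607). With the block 3 fatty acid genes rose and 4 fell, the latter being ACACA (−0.27, blocked adjusted p = 0.014, main 0.0643), SCD (−0.20, 0.0184, main 0.13), ACLY (−0.14, 0.0255, main 0.0642) and FASN (−0.23, 0.031, main 0.144). With the combination against SGI-110 the fatty acid list stood higher with 0 members called (13 of 14 positive, 1 called with the block, median 0.12, camera adjusted p = 4.67e-05, and adjusted p = 0.0265 with an estimated correlation, or 0.0813 over all 30 tests). With ASTX660 against solvent it also stood higher with 0 members called (13 of 14 positive, median 0.13, camera adjusted p = 0.0322), and that call was lost with an estimated correlation (adjusted p = 0.226).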
